A study of Homo sapiens with 10 samples.

How the data were processed

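DNA methylation was profiled by methylated DNA immunoprecipitation followed by sequencing (MeDIP-seq) in HEK293T cells, a human embryonic kidney cell line. In this assay sonicated genomic DNA is captured with an antibody against 5-methylcytosine, and captured fragments pile up as peaks where methylated cytosines are dense. There were 10 samples, an immunoprecipitated (IP) library and an input library for each of 5 conditions, labelled WT, EV, KD, K rep KO and K non-rep KO. The series' design text names the knockdown as that of KCNQ1OT1_K. The labels do not spell out EV, K, rep or non-rep, and these names are kept as given.

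Per the submitters' processing notes, Bowtie2, MACS2 and deepTools were used with the GRCh38 build; versions and settings are not given in the sources used here. The authors deposited 1 narrowPeak list per condition, and whether libraries were pooled is not given in the sources used here. The deposited fold enrichment of each peak is a ratio at the summit over the caller's background. The deposited −log10 p and −log10 q values belong to the same summit, and the lowest −log10 q of the lists lay between 1.30 and 1.31. The deposited score equalled 10 times the −log10 q, cut to a whole number. These per-peak values are the authors' and were used only to describe, rank or filter peaks within a list. The K-KD list was taken as the KD sample. There was 1 further peak list whose name matched no sample label, and it was not used in any step. Peak names inside the K rep KO and K non-rep KO lists carry other prefixes than the lists themselves, so the assignment of these lists to their conditions rests on the lists' names.

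The lists hold no read counts, so depth was worked out from the peaks. Fold enrichment and −log10 p were solved for a whole-number summit pileup and a background, taking fold as (pileup + 1)/(background + 1) and p as an upper Poisson tail, with a tolerance of 0.001. A whole-number solution was found for 99.9% to 100.0% of the peaks of each list. In each list 16.3% to 25.3% of the peaks took a common lowest background, read as the genome-wide background. Other backgrounds lay on regular steps in 68.4% to 75.6% of peaks, where 3.54% to 6.43% would by chance, as they would if an input library had been scaled to the IP library. The genome-wide background divided by the shortest peak length gave IP depth relative to EV, and the step size then gave input depth. Whether the input libraries were the caller's control is not given in the sources used here.

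Peaks on chromosomes 1 to 22 and X were kept, which left out 3.56% to 5.83% of each list. Coordinates are GRCh38 and 1-based. Peaks of 2 lists were called shared with at least 1 bp of overlap. The share of shared peaks was set beside 100 seeded random placements of the peaks, within their chromosome or within their own 1 Mb window. Gene positions came from a RefSeq gene table of GRCh38.p14 with 59084 genes on these chromosomes, 19974 of them protein-coding. A gene region was the gene body plus 2 kb on both sides, because the table gives no strand; the plan had been to add 2 kb upstream alone. Peaks in gene regions also stood in for the promoter peaks planned for imprinted genes. Promoters, exons, introns, CpG islands, base composition and transposons were planned but not analysed here, since they need sequence or transcript models.

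The comparisons were K-KD against EV, K rep KO against WT, K non-rep KO against WT, K rep KO against K non-rep KO, and EV against WT, which were taken as the unperturbed conditions. The pairing follows the order in which the series names the conditions, as the labels do not state it. With 1 list per condition there is no replicate spread and no test across samples, and no p-values are given. Ratios carry exact (Clopper-Pearson) and shares Wilson 95% intervals, which cover counting error only; neighbouring peaks are not independent, so these intervals are too narrow. The relative ratio of a gene list is its ratio of peak numbers, with 0.5 added to both numbers, divided by the ratio over all protein-coding genes. That of a chromosome or window is divided by the ratio over all peaks. The percentile of a gene list is its place among 10000 seeded random lists of the same size, matched on gene length and on peak number.

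Before the data were examined, 12 gene lists were fixed: the KCNQ1OT1 domain with its 11p15.5 neighbours, imprinted genes outside it, germline and cancer-testis genes, heterochromatin and DNA methylation machinery, senescence and secretory genes, innate nucleic acid sensing and interferon genes, housekeeping genes, chromosome 19 zinc finger genes, clustered protocadherin genes, HOX genes, olfactory receptor genes and ribosomal protein genes. All their members were found in the gene table. The rule for named genes was also fixed then. It takes the 10 protein-coding genes with the lowest and the 10 with the highest log2((peaks + 1)/(peaks + 1)) among genes with at least 10 peaks in both lists together, with ties broken by peak number and then symbol. It adds the members of the KCNQ1OT1 domain list, imprinted genes with a peak, and up to 4 members of each other list. Per comparison 1002 to 2574 genes were ranked. Intervals of the lowest and highest genes use the numbers that ranked them and do not allow for that choice. They are therefore no support for a single gene. The 3 lowest and highest 1 Mb windows were taken by the same formula among those with at least 20 peaks. A window among them is not reported here. Windows without a protein-coding gene, the segments of chromosome 11 and the genes named for EV against WT were chosen after the data were seen.

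Alternatives were peaks with −log10 q of 5 or more, peaks with fold enrichment of 4 or more, lists cut to the same length (the 30732 peaks of lowest p in each), all deposited sequences, peaks merged within 500 bp, 50% reciprocal overlap, and summits inside a peak. For gene lists, covered base pairs replaced peak numbers. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9. The steps were tested on simulated data: overlaps matched a brute-force count for 100% of 1615 peaks, simulated pileups were recovered for 100% of 1940 peaks, and gene sets simulated at a relative ratio of 0.5 were recovered at 0.470 (K rep KO against WT) to 0.534 (EV against WT) among 19974 genes.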

Results

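MeDIP peaks were compared between HEK293T cells with a knockdown or knockouts related to KCNQ1OT1 and unperturbed cells. KCNQ1OT1 is a long non-coding RNA transcribed antisense to KCNQ1 within an imprinted domain of chromosome 11. Each of the 5 conditions had 1 IP library and 1 input library, so no value below has a replicate. The lists held 87815 peaks in EV, 53919 in K-KD, 30732 in WT, 53396 in K non-rep KO and 59098 in K rep KO. These covered 64.0, 38.7, 31.2, 39.6 and 44.8 Mb. The median peak was 522 bp wide in EV, 505 bp in K-KD, 748 bp in WT, 506 bp in K non-rep KO and 513 bp in K rep KO. The authors' median fold enrichment lay between 4.08 in WT and 4.44 in K non-rep KO. Relative to EV, IP depth was 0.943 in K-KD, 0.885 in WT, 0.751 in K non-rep KO and 0.90 in K rep KO. Input depth relative to EV was 0.914 in K-KD, 0.684 in WT, 0.999 in K non-rep KO and 1.04 in K rep KO. Peaks lay within protein-coding genes for 56.0% of the EV list, 53.1% of K-KD, 52.2% of K non-rep KO, 52.0% of K rep KO and 41.9% of WT, against 44.3% to 44.5% of randomly placed peaks.

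**Figure D1:**
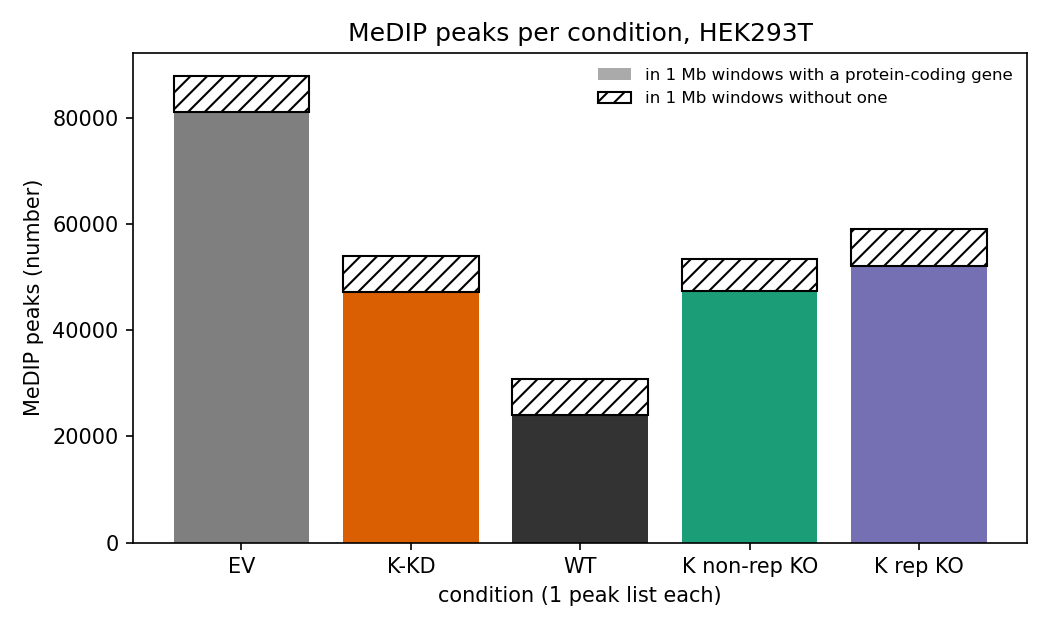
Number of MeDIP peaks on chromosomes 1 to 22 and X in each of the 5 conditions (1 list each); the hatched part counts peaks in 1 Mb windows without a protein-coding gene. The full bars run from 30732 peaks in WT to 87815 in EV, while the hatched parts run from 6013 in K non-rep KO to 7073 in K rep KO.

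KCNQ1OT1 itself (chromosome 11, 2608328 to 2699994) carried few peaks in any list. Within the gene and 2 kb on either side there were 2 peaks in EV, 1 in WT and 0 in K-KD, K rep KO and K non-rep KO. An EV peak at 2674198 to 2674609 had a fold enrichment of 4.33 and lay inside KCNQ1OT1 and KCNQ1. The other EV peak, at 2701031 to 2701537, began 1037 bp past the end of KCNQ1OT1. The WT peak lay at 2654136 to 2654510. These lists hold no RNA or sequence, so the knockdown and the knockouts could not be checked on KCNQ1OT1 itself. KCNQ1 (chromosome 11, 2445008 to 2849105), a potassium channel gene that contains KCNQ1OT1 on the opposite strand, held 45 peaks in EV, 14 in K-KD, 3 in WT, 11 in K non-rep KO and 9 in K rep KO. CDKN1C, a cell cycle inhibitor of the same imprinted domain, held no peak in any list.

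**Figure D2:**
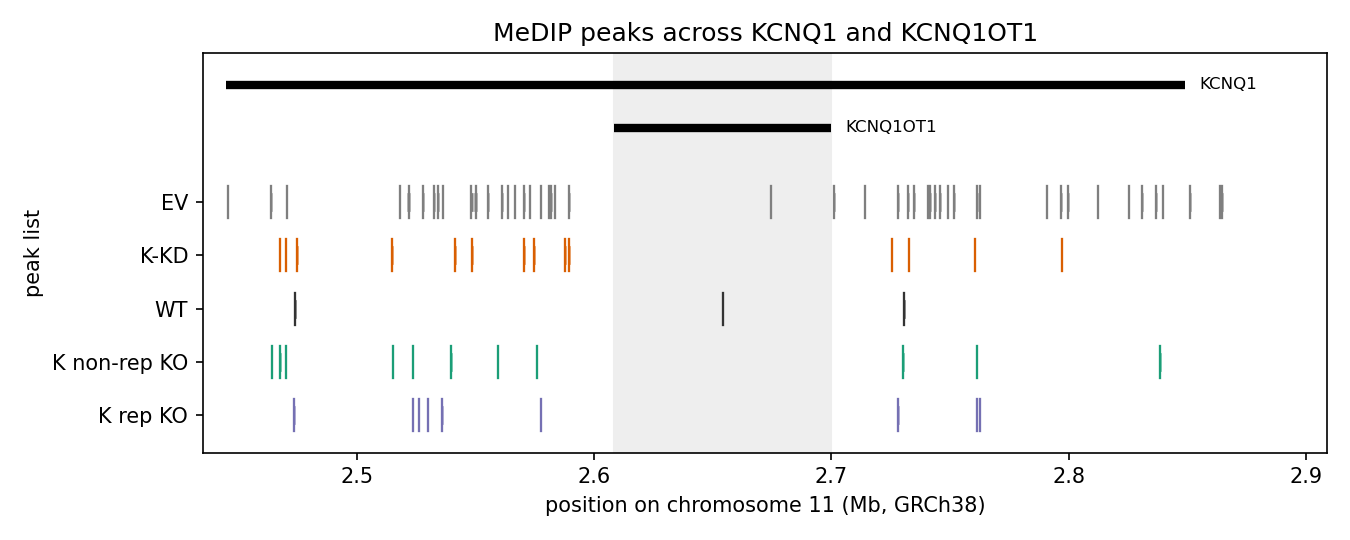
Map of MeDIP peaks (vertical ticks, a row per condition) along KCNQ1 and KCNQ1OT1 on chromosome 11 (GRCh38 position in Mb), with gene extents as black bars and KCNQ1OT1 shaded. KCNQ1 held 45 peaks in EV and 3 to 14 in the other lists, and inside the shaded span only EV and WT had peaks.

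The first comparison asked how peaks in the knockdown, K-KD, differed from those in EV. KIF26B, a kinesin family gene (chromosome 1, 245154985 to 245709432), held 0 peaks in K-KD and 13 in EV (ratio 0, 95% interval 0 to 0.328). PAK2, a serine/threonine kinase, held 0 and 10. TRPV3, a heat-activated ion channel gene, held 1 and 15, and HDLBP, CDC42SE2, TPCN1, ELAVL1, MAPKAP1 and CLMN held 1 each against 10 to 13. SARDH, of sarcosine breakdown, held 3 and 21. At the other end, SREBF2, a regulator of cholesterol synthesis (chromosome 22, 41833105 to 41907305), held 12 peaks in K-KD and 6 in EV. CFAP20DC held 9 and 3, and so did MBTPS1, the protease that activates SREBF2. The remaining genes of this end were CEP89, CTNNA3, FER1L5, FAM168A, NBPF14, ABCA7 and PHF21A, with 7 to 10 peaks in K-KD and 3 or 4 in EV. Intervals of the plain ratio included 1 for these 10 genes, but the ratio over all peaks was 0.614. Those of SREBF2, CFAP20DC, MBTPS1, CEP89, CTNNA3 and FER1L5 lay above 0.614. Among the lowest genes, those of ELAVL1, MAPKAP1 and CLMN included 0.614. NBPF14 belongs to a family of near-identical copies, and its reads are uncertain.

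Over all peaks, inside or outside genes, the K-KD list held 0.614 times the number in EV (0.607 to 0.621). Over protein-coding genes the ratio was 0.583. Of the EV peaks 35.2% were shared, against 3.56% for random placement within chromosomes and 8.53% within 1 Mb windows. In the KCNQ1OT1 domain and its 11p15.5 neighbours, 17 of 23 genes held fewer peaks in K-KD, 2 held more and 4 the same number. Other lists leaned the same way, such as heterochromatin and DNA methylation machinery with 24 genes fewer and 3 more. The 11p15.5 list stood at 3.69 in EV against WT, so its number was also high in EV relative to WT. MRPL23 held 6 peaks against 17, OSBPL5 5 against 12, TRPM5 5 against 11 and CD81 2 against 9. IGF2, the imprinted growth factor gene, held 2 against 6. The 11p15.5 list had 53 peaks against 132, a relative ratio of 0.693 (0.491 to 0.955), at percentile 0.11 of the random lists. Its genes are neighbours, some of them nested, and KCNQ1 alone held 45 of the EV peaks. Random lists take genes from all chromosomes, so that percentile is no fair measure of it. The list's relative ratio was 0.334 with −log10 q of 5 or more. It was 1.08, on the other side of 1, with both lists cut to the same length. Clustered protocadherin genes, cell-surface adhesion genes in tandem arrays, had 35 peaks against 37, a relative ratio of 1.62 (0.993 to 2.65). PCDHGA1 held 17 and 15. Their nested gene regions share peaks, so random lists are no fair measure for them. Housekeeping genes had 20 peaks against 55 (0.634, 0.354 to 1.06), among them RAB7A with 2 against 8 and GPI with 1 against 5. Other lists had relative ratios from 0.776 for olfactory receptor genes to 1.36 for HOX genes, with intervals that included 1. Germline and cancer-testis genes stood at 1.14 (0.835 to 1.54), heterochromatin and DNA methylation machinery at 1.01, and senescence and secretory genes at 0.939. With −log10 q of 5 or more the germline ratio lay above its interval, as given under the processing. Imprinted genes outside 11p15.5 stood at 1.07 (0.834 to 1.35). TRAPPC9 held 27 peaks against 59, WDR27 21 against 28, GRB10 4 against 12, GNAS 1 against 8 and IGF2R 12 against 11. Of the 44 imprinted genes, 36 held a peak in some list, 33 of them in K-KD and 31 in EV. The window with the lowest ratio of K-KD to EV was 185000001 to 186000000 of chromosome 3, with 4 peaks against 36; it holds IGF2BP2, SENP2 and MAP3K13. A gene-free window of chromosome 7, from 59000001 to 60000000, held 240 against 156.

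**Figure D3:**
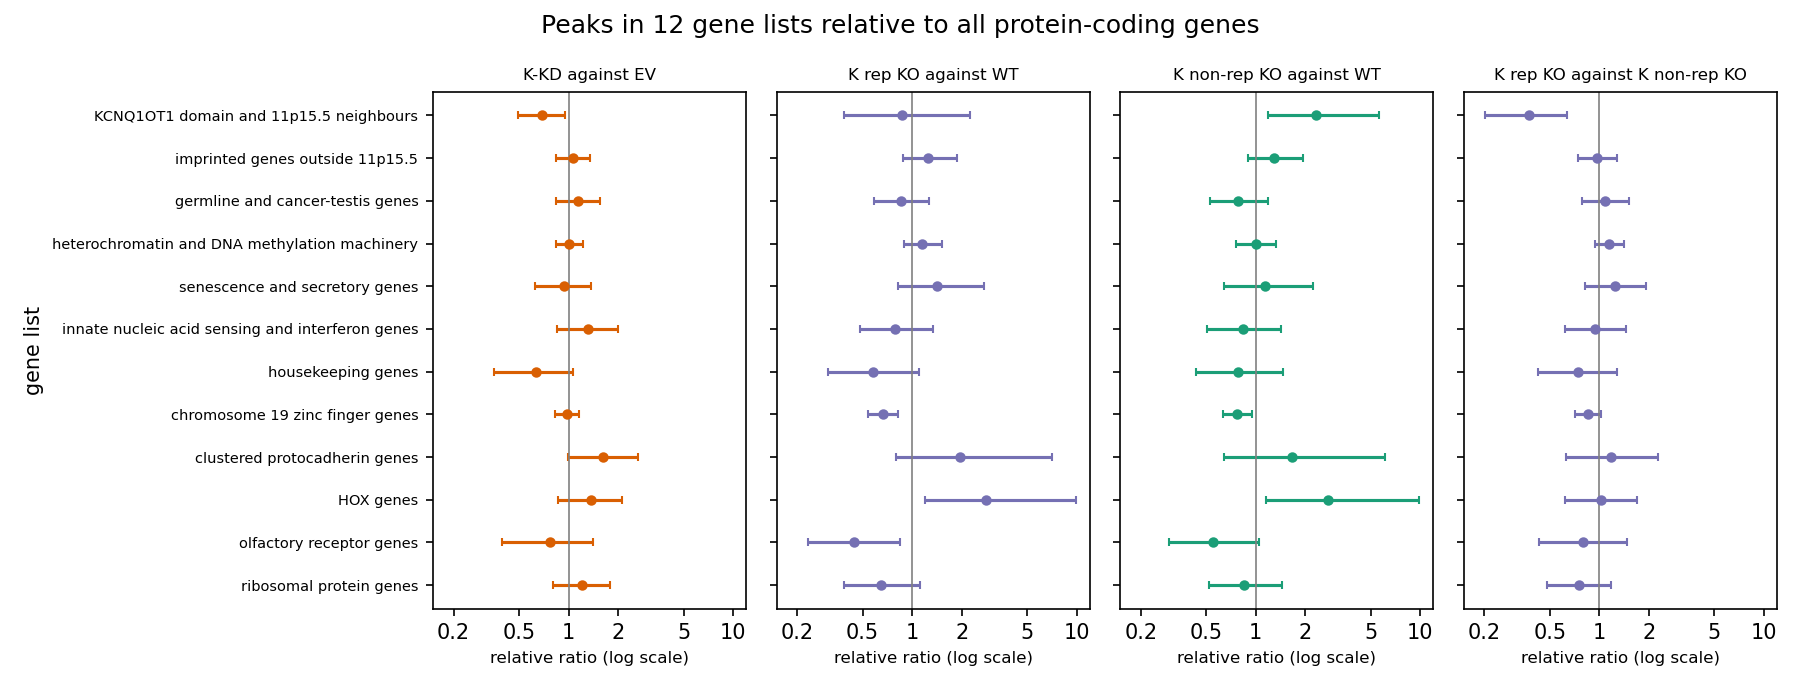
Relative ratio of peak numbers (log scale) in 12 gene lists for 4 comparisons; points are ratios relative to all protein-coding genes and bars are 95% counting intervals. The 11p15.5 list lay at 0.693 in K-KD against EV, 2.33 in K non-rep KO against WT and 0.372 in K rep KO against K non-rep KO.

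The next comparison set K rep KO against WT. HDAC4, a class II histone deacetylase gene (chromosome 2, 239048168 to 239401649), held 40 peaks in K rep KO and 2 in WT. PHF21B held 17 and 0, and GLI2, the transcription factor of hedgehog signalling, held 13 and 0. MAP2K2, a kinase of the MAPK pathway, and RXRA, a nuclear receptor gene, also held 13 and 0. ADCY3, EBF3, ELFN2, NEK6 and NSD2, a histone methyltransferase gene, held 12 and 0. In EV these genes held 7 to 74 peaks, so the low WT numbers also set WT apart from EV. The lowest gene was NBPF19, with 3 peaks against 12 (ratio interval 0.0453 to 0.926). It belongs to the same multicopy family as NBPF14, and its reads are uncertain, as are those of ANKRD36 with 5 against 8. CLSTN1, KATNA1, PEX14, COMMD7, MRPL48, UBE2L3, CERS4 and GLIS3 held 4 to 6 peaks against 6 to 9, with intervals that included 1. Of these, only that of CLSTN1, up to 1.87, lay below the ratio over all peaks, 1.92.

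K rep KO held 1.92 times the peaks of WT (1.90 to 1.95). The WT peaks were wider, and by covered length the ratio was 1.44. Of the WT peaks 63.2% were shared, against 4.58% and 13.5% for random placement within chromosomes and 1 Mb windows. HOX genes, the body-plan transcription factors, had 36 peaks against 5, a relative ratio of 2.81 (1.19 to 9.94). Of these 39 genes 21 held more peaks in K rep KO and 1 fewer. Other lists leaned the same way, such as senescence and secretory genes with 13 more and 0 fewer. HOXB3 held 4 and 0 and HOXD3 3 and 1. With fold enrichment of 4 or more the HOX ratio was 6.46. Without that filter the HOX list stood at 2.33 (1.02 to 8.17) in EV against WT, with 48 peaks against the same 5. Chromosome 19 zinc finger genes, mostly transcriptional repressors, stood at 0.663 (0.539 to 0.819) with 237 peaks against 151, and ZNF787 held 11 and 2. Olfactory receptor genes stood at 0.442 (0.232 to 0.847) with 22 against 21. In EV against WT these 2 lists stood at 0.678 (0.561 to 0.825) and 0.449 (0.257 to 0.817). Ribosomal protein genes stood at 0.646 and housekeeping genes at 0.575, with intervals that included 1. The 11p15.5 list stood at 0.868 (0.385 to 2.24) on 19 peaks against 9, and at 0.316 with lists cut to the same length. Chromosome 11 as a whole stood at 0.532 (0.492 to 0.575). The list's plain ratio of 2.11 was 2.08 times that of the rest of chromosome 11, 1.02. The highest window, 79000001 to 80000000 of chromosome 10 with ZMIZ1 and the surfactant genes SFTPA1, SFTPA2 and SFTPD, held 21 and 1. The 3 lowest windows were all on chromosome 11.

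The comparison of K non-rep KO with WT used the same control. RXRA held 16 peaks in K non-rep KO and 0 in WT, and HDAC4 held 33 and 2. MAP2K2 and NCLN held 13 and 0, ADCY3 12 and 0, and KCNN3, INTS1 and PHF21B 11 and 0. SSBP3 held 21 and 1, and COL6A1, a collagen gene, 10 and 0. These comparisons share the WT list, so part of their overlap comes from WT. SLC43A2, an amino acid transporter gene (chromosome 17, 1569254 to 1630088), held 2 peaks in K non-rep KO and 10 in WT (ratio interval 0.0213 to 0.939), and NBPF19 2 and 12. IL3RA, RPH3AL, SPAG9, ADA2, UBE4B, CATSPERD, GAS7 and ANKRD36 held 4 or 5 against 8 to 10, with intervals that included 1. Those of IL3RA, RPH3AL and SPAG9 lay below the ratio over all peaks, 1.74.

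K non-rep KO held 1.74 times the peaks of WT (1.71 to 1.76) and 1.27 times its covered length. Of the WT peaks 59.9% were shared, against 4.07% and 11.5% for random placement within chromosomes and 1 Mb windows. The 11p15.5 list had 47 peaks against 9, a relative ratio of 2.33 (1.18 to 5.65) at percentile 99.9. Its genes are neighbours, so that percentile is no fair measure. In this list 13 genes held more peaks in K non-rep KO and 1 fewer, beside 11 and 0 of senescence and secretory genes. With −log10 q of 5 or more the 11p15.5 ratio was 1.04. MRPL23 held 9 and 0, OSBPL5 7 and 2, and LSP1 6 and 1. HOX genes stood at 2.76 (1.15 to 9.82) with 32 peaks against 5, beside 2.33 in EV against WT at the same setting. With fold enrichment of 4 or more the ratio of K non-rep KO to WT was 6.52. Chromosome 19 zinc finger genes stood at 0.774 (0.631 to 0.955), olfactory receptor genes at 0.553 (0.298 to 1.04) and innate nucleic acid sensing and interferon genes at 0.832 (0.504 to 1.43), where CGAS, the cytosolic DNA sensor, held 6 and 5. The 11p15.5, zinc finger and olfactory lists lay on the same side of 1 in EV against WT. Chromosome 18 had the lowest relative ratio, 0.587 (0.539 to 0.640), and other chromosomes lay between 0.842 and 1.27. It was also lowest apart from chromosome 11 in K rep KO against WT, at 0.560, and lowest in EV against WT, at 0.454, so the difference lay with the WT list.

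The knockouts were then set against each other. Among the 10 genes with the fewest peaks in K rep KO relative to K non-rep KO, 4 lay on chromosome 11. CPT1A, which brings fatty acids into mitochondria (chromosome 11, 68754620 to 68844277), held 3 and 11, and SHANK2, a synaptic scaffold gene (70467854 to 71253234), held 6 and 17. PTDSS2 held 2 and 9 and SBF2 3 and 10. Elsewhere SSU72, a phosphatase of RNA polymerase II, held 3 and 13, and DNAAF9, CAMSAP1, SKI, ADD1 and UNC13D held 2 to 4 against 9 to 13. Ratio intervals included 1 for CPT1A, PTDSS2, SBF2, DNAAF9, CAMSAP1, ADD1 and UNC13D. Those of CPT1A, PTDSS2, DNAAF9 and CAMSAP1 lay below the ratio over all peaks, 1.11. With −log10 q of 5 or more the relative ratio of SKI was 1.07, on the other side of 1. CTBP2, a transcriptional corepressor gene (chromosome 10, 124984317 to 125162463), held 23 in K rep KO and 6 in K non-rep KO (ratio interval 1.52 to 11.5). UBE3C, a ubiquitin ligase gene, held 13 and 2, CLUH 10 and 1, TMEM117 9 and 1, and MAGI1 11 and 2. CDC27, ZNF282, ATP2A3, EML1 and FBXO21 held 9 or 10 against 2, and intervals of the last 3 included 1. Those of CDC27 and ZNF282 included 1.11.

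K rep KO held 1.11 times the peaks of K non-rep KO (1.09 to 1.12) and shared 48.8% of them, against 4.02% and 10.2% for random placement within chromosomes and 1 Mb windows. Chromosome 11 had 1321 peaks in K rep KO and 2146 in K non-rep KO, a relative ratio of 0.556. Every other chromosome lay between 0.949 and 1.13. The ratio was 0.481 (0.422 to 0.549) below 50 Mb, 0.953 (0.805 to 1.13) from 50 to 55 Mb around the centromere, and 0.507 (0.461 to 0.558) above 55 Mb. All 25 windows of 5 Mb with at least 20 peaks lay below 1, from 0.301 to 0.953. The 11p15.5 list had 19 peaks against 47, a relative ratio of 0.372 (0.203 to 0.636) below all of the random lists. It was 0.169 with lists cut to the same length and 0.772 with −log10 q of 5 or more. The random lists were not limited to chromosome 11 or to neighbouring genes. The list's plain ratio of 0.404 was 0.652 times that of the rest of chromosome 11, 0.620. In the 11p15.5 list MRPL23 held 0 and 9, TNNT3 0 and 3 and OSBPL5 4 and 7. Other lists stood between 0.739 for housekeeping genes and 1.24 for senescence and secretory genes, with intervals that included 1; the latter stood at 2.93 with −log10 q of 5 or more.

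**Figure D4:**
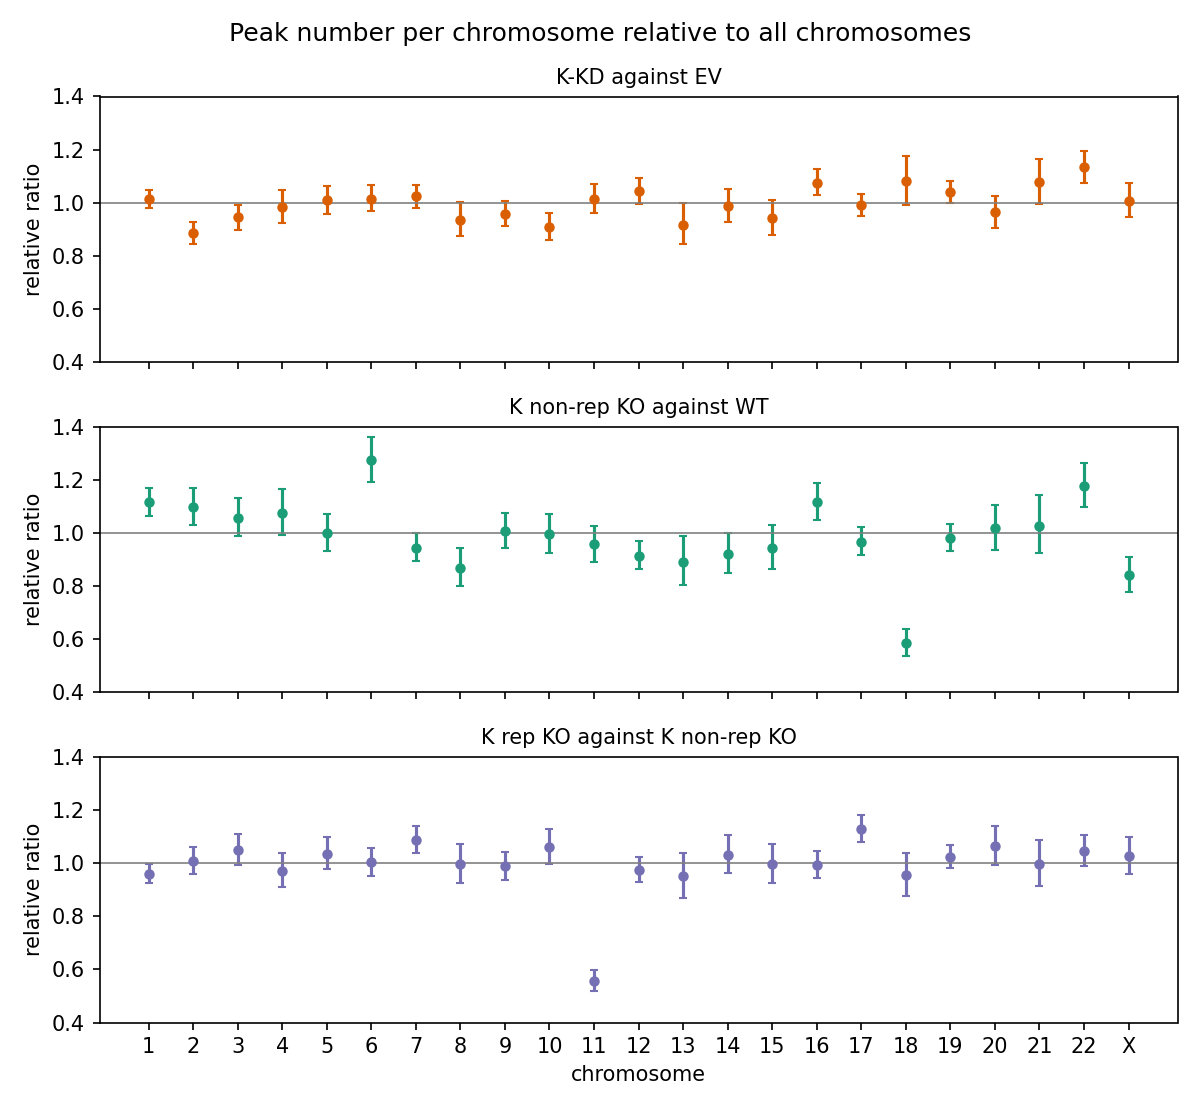
Ratio of peak numbers per chromosome divided by the ratio over all chromosomes, in 3 comparisons (points, with 95% counting intervals as bars). Chromosome 11 lay at 0.556 in K rep KO against K non-rep KO and at 1.02 in K-KD against EV, and chromosome 18 lay at 0.587 in K non-rep KO against WT. The 1.02 joins 2.09 (1.78 to 2.47) from 50 to 55 Mb and 0.931 (0.879 to 0.985) in the rest of chromosome 11.

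**Figure D5:**
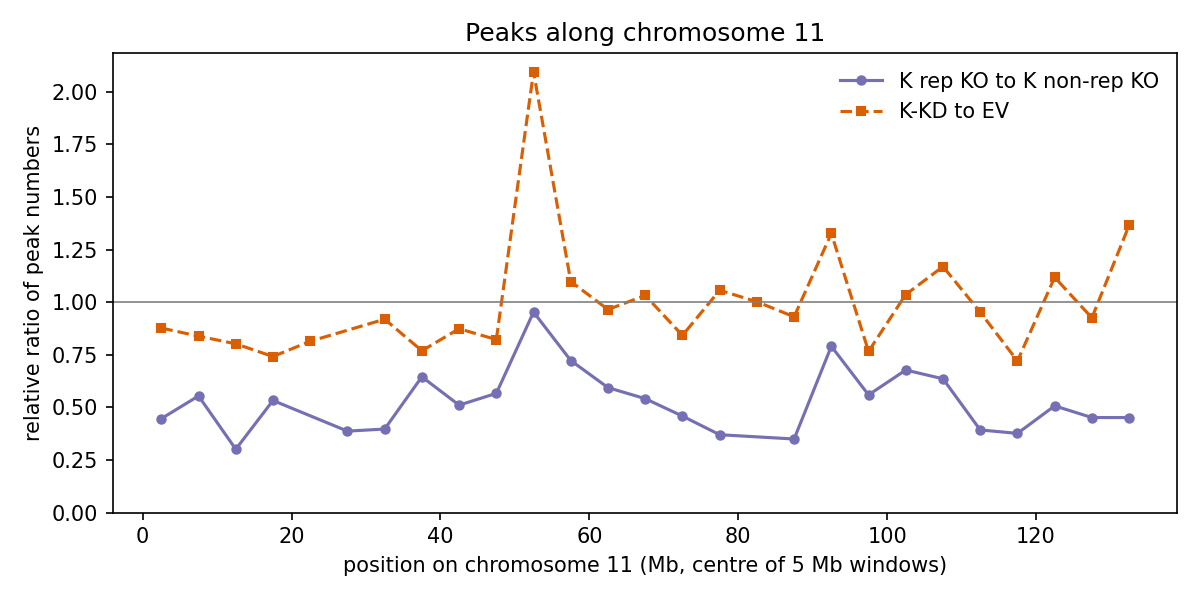
Relative ratio of peak numbers in 5 Mb windows along chromosome 11 for K rep KO to K non-rep KO (circles) and K-KD to EV (squares), for windows with at least 20 peaks in both lists together. The circles lay below 1 in all 25 windows and were closest to it, at 0.953, from 50 to 55 Mb.

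The spread between the conditions taken as unperturbed was read from EV against WT. RXRA held 29 peaks in EV and 0 in WT, HDAC4 74 and 2, and HIPK2, a nuclear kinase gene, 22 and 0. IQSEC1 held 57 and 2 and BAIAP2 37 and 1. ADA2 held 5 and 8. EV held 2.86 times the peaks of WT (2.82 to 2.89). This was a larger factor than in any comparison of a perturbed condition with its control. By covered length the factor was 2.05. Of the WT peaks 68.6% were shared with EV. The 11p15.5 list stood at 3.69 (1.98 to 8.67) with 132 peaks against 9, HOX genes at 2.33, chromosome 19 zinc finger genes at 0.678 and olfactory receptor genes at 0.449. Innate nucleic acid sensing and interferon genes stood at 0.565 (0.349 to 0.957) with 54 peaks against 25. Chromosome 11 stood at 0.967 (0.907 to 1.03) in this comparison. Its segment from 50 to 55 Mb stood at 0.252 (0.214 to 0.296), and the rest of the chromosome at 1.25 (1.16 to 1.34).

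Across the 5 lists there were 144156 distinct regions, of which 11493 had a peak in every list. Of the 20284 regions found in both EV and WT, 70.7% also had a peak in K-KD, 79.6% in K rep KO and 76.9% in K non-rep KO. Regions absent from both EV and WT numbered 2395 in K-KD and K rep KO alone, 1880 in K-KD and K non-rep KO alone, 2326 in K rep KO and K non-rep KO alone, and 932 in these 3 lists. Of regions with a peak in EV and WT, 960 were kept in K non-rep KO and absent from K-KD and K rep KO, and 1163 were kept in K rep KO and absent from K-KD and K non-rep KO.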

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

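The tests of input depth and of the spread between EV and WT were set after their results were seen. The K-KD list held 0.614 times the peaks of EV. The K rep KO list held 1.92 times and the K non-rep KO list 1.74 times the peaks of WT. By covered length these ratios were 0.605, 1.44 and 1.27. The ratios of peak numbers were singled out because they point in opposite directions from their controls. The difference between them was not tested, as each condition has 1 list.

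Fewer peaks in K-KD than in EV do not go back to IP depth alone. EV summits thinned to the K-KD depth still passed the lowest p of the K-KD list in 97.4% of cases, where K-KD held 61.4% of the EV number, and K rep KO held more peaks than K-KD from a shallower IP library. The thinning looks at summits and not at peak length, so the share is an upper bound. Differences between libraries unrelated to the knockdown may still account for it, since EV and WT differ by a factor of 2.86. An effect of the knockdown stays open and was not tested.

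The low number in WT is likewise not explained by IP depth alone, as 93.7% of EV summits thinned to the WT depth passed the lowest p of the WT list and K non-rep KO held more peaks from a shallower IP library. A shallower input library is a possible explanation. The WT input had 0.684 times the EV depth, the lowest of the 5, but WT peaks took the genome-wide background in 17.7% of cases and K rep KO peaks in 16.3%, so the test did not decide it. No biological explanation was tested for this pattern, and both knockout ratios above 1 rest on this WT list.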

How the results depend on the processing

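Leaving out windows without a protein-coding gene, or chromosome 11, was chosen after the data were seen; the other alternatives were chosen before. No paired analysis was possible because the labels carry no replicate numbers and each condition has 1 library, which also rules out leaving out a replicate. Promoter-only gene regions and the LINE-1 alternatives were not run. Apart from lists cut to the same length, where the ratio of peak numbers is 1.00 in the 5 comparisons by construction, the ratios stayed on their side of 1. Lower numbers under stricter thresholds follow from the filter; elsewhere the cause was not tested. Depth limits the weaker peaks most, and counting intervals do not cover differences between libraries.

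With −log10 q of 5 or more, peaks numbered 37888 in EV, 17368 in K-KD, 13776 in WT, 18307 in K non-rep KO and 24009 in K rep KO, covering 35.7, 17.6, 19.1, 19.9 and 25.4 Mb. Of these 54.5%, 48.2%, 39.6%, 47.9% and 47.3% lay within protein-coding genes. The ratio of peak numbers was 0.458 for K-KD against EV, 1.74 for K rep KO and 1.33 for K non-rep KO against WT, 1.31 between the knockouts and 2.75 for EV against WT. Shared were 26.0% of EV peaks with K-KD, 66.6% of WT peaks with K rep KO, 54.1% of K non-rep KO peaks with K rep KO and 69.3% of WT peaks with EV. The relative ratio of the 11p15.5 list was 0.334 (K-KD against EV), 1.04 (K non-rep KO against WT) and 0.772 (between the knockouts). That of imprinted genes was 0.888 (K non-rep KO against WT), of germline genes 1.73 (K-KD against EV), of senescence genes 2.93 (between the knockouts) and of protocadherins 0.619 (K rep KO against WT). Main values of imprinted genes, 1.29 (0.897 to 1.93), and protocadherins, 1.96 (0.795 to 7.07), lay on the other side of 1. The latter rested on 25 peaks against 5. Chromosome 11 stood at 0.926 (K-KD against EV) and chromosome 18 at 0.611 (K rep KO) and 0.395 (EV) against WT.

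With fold enrichment of 4 or more, peaks numbered 51589 in EV, 28769 in K-KD, 16116 in WT, 32255 in K non-rep KO and 37233 in K rep KO. EV, K-KD and WT covered 42.0, 22.7 and 18.9 Mb. Within protein-coding genes lay 57.2%, 55.3%, 46.2%, 53.6% and 53.0% of the 5 lists in that order. The ratio of peak numbers was 0.558 for K-KD against EV, 2.31 for K rep KO and 2.00 for K non-rep KO against WT, 1.15 between the knockouts and 3.20 for EV against WT. Shared were 25.9% of EV peaks, 58.9% (K rep KO), 55.7% (K non-rep KO) and 61.2% (EV) of WT peaks, and 42.7% of K non-rep KO peaks. Chromosome 18 stood at 0.990 (K-KD against EV) and 0.409 (EV against WT).

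With lists cut to 30732 peaks, 40.7% of EV peaks were shared with K-KD, 47.4% of WT peaks with K rep KO, 45.8% with K non-rep KO and 43.4% with EV, and 45.0% of K non-rep KO peaks with K rep KO. EV covered 31.0 Mb and K rep KO 29.6 Mb. Within protein-coding genes lay 53.5% of EV, 51.5% of K-KD, 51.0% of K non-rep KO and 48.9% of K rep KO peaks. The 11p15.5 list went to the other side of 1 in K-KD against EV, at 1.08, and stood at 0.316 (K rep KO against WT) and 0.169 (between the knockouts). Heterochromatin genes stood at 0.809 and chromosome 19 zinc finger genes at 0.749 (K-KD against EV), and senescence genes at 1.94 (between the knockouts). Chromosome 11 stood at 1.1 (K-KD against EV), 0.460 (K rep KO), 0.884 (K non-rep KO) and 0.823 (EV against WT). Chromosome 18 stood at 0.975 (K-KD against EV), 0.638 (K rep KO against WT) and 1.05 (between the knockouts).

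By 50% reciprocal overlap, 23.1% of EV peaks, 45.0% (K rep KO), 43.4% (K non-rep KO) and 47.5% (EV) of WT peaks, and 33.9% of K non-rep KO peaks were shared. By summits the shares were 28.6%, 56.5%, 52.7%, 61.7% and 42.9% in that order. Merging within 500 bp gave an EV to WT ratio of 2.81 and shares of 35.6% (EV with K-KD), 60.6% (WT with K non-rep KO) and 69.2% (WT with EV). With all sequences the ratios to WT were 1.89 (K rep KO), 1.71 (K non-rep KO) and 2.80 (EV), and 49.3% of K non-rep KO peaks were shared. Without windows lacking a protein-coding gene the ratios were 0.583 (K-KD to EV), 2.16 (K rep KO), 1.97 (K non-rep KO) and 3.36 (EV) to WT, and the shares 32.7% (EV with K-KD), 61.1% (WT with K rep KO), 69.4% (WT with EV) and 45.7% (between the knockouts). Without chromosome 11 K rep KO stood at 1.96 to WT and 1.13 to K non-rep KO, with shares of 63.8% and 49.5%. Of the named genes' values under alternatives, 288 stayed within the interval of the main value, 9 left it, and that of SKI between the knockouts went to the other side of 1, at 1.07, with −log10 q of 5 or more.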

Other observations

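The split by gene content, the chromosome 11 test above 55 Mb, and the further cutoffs, the second reference and the comparison with other lists in the background test were chosen after results were seen. Peaks in 1 Mb windows without a protein-coding gene were similar in number across lists. They numbered 6733 in EV, 6639 in K-KD, 6632 in WT, 6013 in K non-rep KO and 7073 in K rep KO. The ratio of K-KD to EV was 0.986 (0.953 to 1.02) in these windows and 0.583 (0.577 to 0.590) in the rest of the genome. For EV against WT it was 1.02 (0.981 to 1.05) and 3.36 (3.32 to 3.41). Against WT, K rep KO stood at 1.07 (1.03 to 1.1) and 2.16 (2.13 to 2.19), and K non-rep KO at 0.907 (0.875 to 0.939) and 1.97 (1.94 to 2.00). K rep KO to K non-rep KO went the other way, with 1.18 (1.14 to 1.22) in these windows and 1.1 (1.08 to 1.11) elsewhere. The windows made up 7.67% of the EV list and 21.6% of the WT list. Several lie at centromeres, such as 59000001 to 60000000 of chromosome 7 with 156 peaks in EV, 240 in K-KD, 230 in WT, 145 in K non-rep KO and 237 in K rep KO. Reads from satellite repeats map uncertainly there.

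Of 40 genes of the DNA methylation and heterochromatin machinery, 33 held a peak in EV, 29 in K-KD, 25 in WT, 30 in K non-rep KO and 31 in K rep KO. KDM4B, a histone demethylase gene and the member with the most peaks, held 59 in EV, 32 in K-KD, 12 in WT, 28 in K non-rep KO and 45 in K rep KO. EHMT1, a histone methyltransferase gene, held 46, 33, 11, 23 and 31 in the same order. DNMT1, the maintenance DNA methyltransferase, held 18, 9, 1, 9 and 11. Among germline genes TEX14 held 20, 11, 6, 13 and 10, and among secretory genes TIMP2 held 24, 13, 8, 14 and 19.

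The chromosome 11 deficit of K rep KO against K non-rep KO was weighed against list length, a change near KCNQ1OT1, a loss of methylated DNA and a loss of copies. List length or threshold did not account for it, as the relative ratio was 0.521 with lists cut to the same length, 0.578 with −log10 q of 5 or more and 0.557 with fold enrichment of 4 or more, nor did a change limited to the KCNQ1OT1 neighbourhood, as the ratio above 55 Mb was 0.507. Fewer chromosome 11 copies in the K rep KO cells, or in part of them, may account for it: chromosome 11 peaks took the genome-wide background 28.5 percentage points more often than peaks elsewhere in K rep KO (25.5 to 31.5), against 5.23 to 10.3 in the other 4 lists. This speaks to copies only if the caller's background came from the input, which is not known. With a background from the IP library, less methylated DNA could raise that share as well. Less methylated DNA without a loss of copies stays open: in regions shared with EV the K rep KO background on chromosome 11, relative to other chromosomes, was 0.766 (0.755 to 0.774), below the bound of 0.8 set beforehand, but that bound took no account of K-KD, WT and K non-rep KO, which lay at 0.838 to 0.889, and over 10 settings (5 background cutoffs, EV or K non-rep KO as reference) K rep KO was lowest in 8 and its interval lay below those of the other lists in 3. With 1 library the loss of copies is a hypothesis, and the knockout itself is an untested alternative.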
